A study of Mus musculus with 20 samples.

How the data were processed

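RNA sequencing libraries from whole spleens of mice aged 4 weeks were compared between control mice and mice bred on a gluten-free diet. The labels give 20 libraries, 11 control and 9 gluten-free. Each library carries an ID that is either a plain number (8 control, IDs 1 to 8, and 4 gluten-free, IDs 7 to 10) or a number after the letter S (3 control, IDs S1, S2 and S6, and 5 gluten-free, IDs S1, S3, S5, S6 and S8). The meaning of the letter is not stated, so the ID form was treated as a possible cohort or batch and each diet comparison was also made within each form. The labels do not state that each ID is a separate mouse or which mice were litter mates, so the p-values of the gene fits and permutation tests measure the spread between these libraries. Fisher's exact tests count genes of the same libraries as independent, so their p-values do not measure that spread.

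The values analysed are the raw counts per gene deposited by the authors, as whole numbers with no normalization. Per the submitters' processing notes, reads were processed with CASAVA, aligned with HISAT2 2.0.5 to GRCm38 (mm10) and counted with featureCounts 1.5.0. The strand setting, the annotation release and the treatment of reads that match several places are not stated, so values of near-identical paralogs and of overlapping antisense genes are less certain than the others. The file held 54532 genes, of which 33089 had at least 1 count. Library totals ran from 13626000 (control 6) to 24268200 (gluten-free S3) counts. Counting noise was small against the differences between libraries: in 47 pairs of libraries of the same diet and ID form, chi-square per degree of freedom ran from 6.12 to 103.

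Differences between groups were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit and test, two-sided), with TMM library scaling and the default expression filter, which left 17600 genes. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The fit over all libraries held the diet and the ID form as terms. Further fits tested the ID form, the interaction of diet and ID form, and the diet within the plain IDs and within the S IDs. Expression is given as TMM-scaled CPM, the usual library-size units, log2 CPM used a prior count of 2, and the error beside a log2 fold change is its standard error, computed as the absolute log2 fold change over the square root of the F statistic. Fold changes are gluten-free minus control.

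A set of 51 gene lists (cell types of the spleen and of neighbouring tissues, immune responses, gut and coeliac genes, metabolism and stress) was fixed, of which 48 had at least 3 members among the tested genes. The islet list (0 of 8 genes measured), the liver list (1 of 10) and the list of female and male specific genes (2 of 6) were not tested as lists. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, with fry, and by an exact permutation test of the mean log2 CPM of each list, with adjustment over the 48 lists. Sample measures were compared by exact permutation of the library labels, two-sided, over all libraries (167960 splits), within the ID forms (27720 splits), within the plain IDs (495 splits, smallest possible p 0.00202) and within the S IDs (56 splits, smallest possible p 0.0179).

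Genes named for the pooled comparison follow a rule: the 10 highest and 10 lowest fold changes among called protein-coding genes with a mean of at least 1 CPM and the same direction in both ID forms. If fewer than 5 genes met it, the 10 smallest p-values among genes that met the other conditions were named as not past the threshold. Up to 3 members of each list and a few fixed genes (Klrk1, Foxp3, Il10, Ifng, Tnf, Tgm2) were added, with Xist. Called genes numbered 0, so the second part applied. The libraries, comparisons, tests, lists, naming rule and most alternatives were set before the data were examined. The choice to describe the plain IDs at length, with their 10 highest and 10 lowest called genes and 3 members per list, was made after the counts had been seen.

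Alternatives were other scalings (RLE, upper quartile), no filter or a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom with and without quality weights, a robust fit, no term for the ID form, each ID form alone, a replicate block over the 4 shared IDs, covariates for sex genes, acinar genes and erythroid genes, 1 surrogate variable from sva 3.50.0, protein-coding genes alone, leaving out haemoglobin, immunoglobulin and acinar genes, other thresholds, and leaving out each library in turn. After the data had been seen, control 5 was also counted with the S IDs, control 5 and gluten-free S1 were left out together, the share of rRNA-like genes was used as a covariate, and the erythroid covariate and several other alternatives were applied within the ID forms. Random splits of the libraries were drawn 100 times with a fixed seed, or enumerated where there were only 56.

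The pipeline was tested on simulated data with the real group sizes, 17600 genes and 200 changed genes. Each gene was drawn independently, with the spread left after fitting the diet, the ID form and their interaction. The simulated pooled diet effect was the same in both ID forms. The real pooled fit had no interaction term, so the simulated recovery may overstate what it could find. In the fit over all libraries the pipeline recovered 55.2% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 95.5% of those changed 4-fold, with 3.57% false calls. For the ID form the values were 61.2%, 91.0% and 98.5%, with 4.02% false calls. The interaction gave 5.97%, 26.9% and 72.7% (5.41% false), the plain IDs 26.9%, 65.7% and 90.9% (3.94% false), and the S IDs 10.4%, 59.7% and 90.9% (5.31% false). A simulated rise of the 17 T cell genes was called by camera (adjusted p = 8.14e-22), and 0 other lists of the 48 were called at an adjusted p under 0.05. As the simulated genes varied independently, this does not show how camera acts on genes that vary together. In the real data, random splits of the libraries gave a median of 15 lists called by camera.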

Results

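The spleen is a blood-filtering and immune organ that in young mice also forms red blood cells. Whole spleen RNA was sequenced from 11 control libraries and 9 libraries of mice bred on a gluten-free diet, all at age 4 weeks. Of the control libraries 8 had plain number IDs and 3 had IDs that begin with S, and of the gluten-free libraries 4 had plain and 5 had S IDs. Library totals averaged 16313500 ± 1976580 counts (SD, n = 11) in control and 20162200 ± 2458040 counts (SD, n = 9) in gluten-free libraries. Xist, the RNA that silences an X chromosome in females, lay between 863 and 1375 CPM of the library total in each library. The Y-linked genes Ddx3y, Kdm5d and Uty had 0 counts and Eif2s3y had 1 count over the 20 libraries. Il17a, an inflammatory cytokine gene, also had 0 counts over the 20 libraries, which does not exclude a level too low to be counted at this depth.

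The pooled comparison asked how spleens of mice bred on the gluten-free diet differed from control spleens across both ID forms. The genes with the smallest p-values included lysozyme genes, chemokines and an alarmin, most of them higher with the gluten-free diet, but 0 of 17600 genes passed the threshold in edgeR (4485 genes at an unadjusted p under 0.05, where 880 would be expected by chance, and 1 gene at an adjusted p under 0.1). Lyz1 (ENSMUSG00000069515, chromosome 10, 117287797 to 117292868), a lysozyme gene, averaged 10.5 ± 3.29 CPM (SD, n = 11) in control and 21.1 ± 4.75 CPM (SD, n = 9) in gluten-free libraries, with a log2 fold change of 1.00 ± 0.16 (SE, adjusted p = 0.0629). Its near-identical neighbour Lyz2, the myeloid lysozyme, had a log2 fold change of 0.73 ± 0.14 (SE), and how reads that match both were counted is not stated. The T cell chemokine genes Cxcl16 and Cxcl9 had log2 fold changes of 0.51 and 0.90, and the alarmin gene Il33 had 0.88. Thbs4, a matrix protein gene, had 1.08, Madcam1, the gut-homing addressin of endothelium, had 0.95, the growth factor gene Nrg1 had 1.05, and Sergef had 0.54. Ssh1, an actin-regulating phosphatase gene, had a log2 fold change of -0.36 ± 0.07 (SE). The adjusted p of these 9 genes after Lyz1 was 0.102.

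Among the genes fixed for their relation to coeliac disease and T cells, none passed the threshold in this edgeR fit. Foxp3, the master regulator of regulatory T cells, had a log2 fold change of 0.50 (adjusted p = 0.197), the cytokine gene Il10 had 0.90 (adjusted p = 0.185) and Ifng had 0.53 (adjusted p = 0.406). Tnf had 0.63 (adjusted p = 0.102). Klrk1, which encodes the NKG2D receptor of cytotoxic cells, had -0.26 (adjusted p = 0.210), Tgm2, the transglutaminase that is the autoantigen of coeliac disease, had -0.27 (adjusted p = 0.106), and Xist had -0.06 (adjusted p = 0.714).

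Gene lists differed by diet in the pooled comparison in 1 of 4 tests. In camera with its preset correlation, 27 of 48 lists passed the threshold, 20 higher (T cell genes among them) and 7 lower (red cell precursor and cell cycle genes among them). None did with an estimated correlation (smallest adjusted p = 0.449 with an estimated correlation), with fry (smallest adjusted p = 0.0575), or in the exact permutation test of list means (smallest adjusted p = 0.109). Over all genes 0 members of any list were called, and the member counts that follow are those adjusted over the list alone. Of the T cell list 17 of 17 members were higher (median log2 fold change 0.53, camera adjusted p = 1.5e-09, adjusted p = 0.449 with an estimated correlation), Trac among them with 0.70. Of the regulatory T cell list 9 of 13 were higher (median 0.58), with Il2ra at 0.71 and Tnfrsf9 at 0.87, and of the naive T cell list 5 of 10. The gamma-delta T cell list had 0 of 7. The coeliac disease associated genes, fixed as a list, had 10 of 18 members higher, such as Themis (0.62) and Ctla4 (0.64), and 1 lower. The gut homing list had 1 of 11 higher and 1 lower, with Ccr9, which guides lymphocytes to the small intestine, at 0.67.

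B cell and myeloid lists also passed in camera alone. The follicular and marginal zone B cell list had 0 of 17 members called over the list alone, with S1pr3 at 0.64, the plasma cell list 0 of 15 and the immunoglobulin constant region list 1 of 11 higher, with Igha, the IgA heavy chain, at 0.85. The neutrophil list had 4 of 20 higher (median 0.78, adjusted p = 0.549 with an estimated correlation), the monocyte list 3 of 12, and the plasmacytoid dendritic cell list 5 of 10, with Ly6d at 0.56. The lists of megakaryocytes and platelets and of mast cells, basophils and eosinophils had 0 of 14 and 0 of 10. Higher lists of responses were the interferon gamma and antigen presentation list (1 of 24, Nlrc5 at 0.65), the inflammatory cytokine list (4 of 15), the anti-inflammatory list (2 of 9, Socs3 at 0.57), the immediate early genes (3 of 20 higher, 1 lower), the circadian clock (0 of 16) and glycolysis (6 of 16 higher, 1 lower). Across all 27 lists the adjusted p with an estimated correlation lay between 0.449 and 0.549.

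The lower lists were led by the erythroid list, with 21 of 21 members lower over the list alone (median log2 fold change -0.79, camera adjusted p = 6.61e-13, adjusted p = 0.449 with an estimated correlation). Car1, the carbonic anhydrase of red cell precursors, had -0.97 and Tspo2 had -0.83. The cell cycle list had 26 of 26 lower (median -0.63, camera adjusted p = 2.32e-13, adjusted p = 0.449 with an estimated correlation), with the DNA synthesis genes Rrm2 at -0.75 and Mcm2 at -0.64. Lower by camera were also heat shock (0 of 14), fatty acid oxidation (5 of 17), nuclear oxidative phosphorylation genes (0 of 22), ribosomal proteins (0 of 28), and iron and haem handling (5 of 15 lower, 1 higher). The other 21 lists had camera adjusted p from 0.0600 to 0.893: Th1, Th2 and Th17 genes, NK and cytotoxic cells, the NKG2D receptor and ligands, germinal centre B cells, red pulp and marginal zone macrophages, conventional dendritic cells, haematopoietic progenitors, the type I interferon response, aryl hydrocarbon receptor targets, the unfolded protein response, the glucocorticoid response, cholesterol synthesis, fatty acid synthesis, the mitochondrial genome, pancreatic acinar cells, adipocytes, fibroblasts, endothelium, smooth muscle, skeletal muscle and mesothelium. The NK receptor genes Klra4 and Klre1 were lower over the list of NK and cytotoxic cells alone, at -1.02 and -0.69.

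The pooled count of genes rested on single libraries and on the tool: without control S6 3765 genes were called and without gluten-free S8 2990 genes, and DESeq2 called 1593 genes (407 higher, 1186 lower), limma-voom 1 and limma-voom with quality weights 9572. With the erythroid mean as a covariate 1 of the 27 lists kept its camera call and direction and 6 were called in the opposite direction, and in the S IDs alone 3 kept it and 8 were called in the opposite direction.

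Within the plain IDs (8 control and 4 gluten-free libraries) the diets differed widely: 7288 of 17600 genes were called, 3257 higher and 4031 lower with the gluten-free diet, and 3676 of them by at least 1.5-fold. Called genes of neutrophil granules, megakaryocytes, T cells, immunoglobulins and the capsule were mostly higher. Those of red cell precursors, of DNA replication and of oxidative phosphorylation were mostly lower. Over all protein-coding genes tested 21.1% were called higher and 25.0% lower, so member counts near those shares say little about a list. As lists, 0 of 48 passed in camera with an estimated correlation (smallest adjusted p = 0.205). In the neutrophil list 19 of 20 members rose (19 adjusted over the list alone, median log2 fold change 1.66). Mpo, the granule enzyme myeloperoxidase (ENSMUSG00000009350), rose from 72.5 ± 28.3 CPM (SD, n = 8) to 288 ± 107 CPM (SD, n = 4), a log2 fold change of 1.97 ± 0.29 (SE, adjusted p = 6.69e-05). The granule genes Prtn3, Ltf and Chil3 rose by 1.83, 1.78 and 1.67 on the log2 scale. The megakaryocyte and platelet list had 14 of 14 members higher (median 1.01), with Thbs1 at 1.00 and the clotting factor gene F5 at 0.99. Of the list of mast cells, basophils and eosinophils 7 of 10 rose (7 over the list alone), such as the basophil protease gene Mcpt8 (1.71), and of the monocyte list 7 of 12 rose (8 over the list alone), with Lyz2 at 1.07 and F13a1 at 1.44. The red pulp and marginal zone macrophage list had 2 of 17 higher (1 over the list alone, median 0.04). Of capsule and stroma, the mesothelium list had 6 of 10 higher (10 over the list alone, median 0.87, adjusted p = 0.417 with an estimated correlation) and the fibroblast list 7 of 15 (8 over the list alone, median 0.58, adjusted p = 0.352 with an estimated correlation). Where 1 member count of a list is given here, the count adjusted over the list alone was the same.

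Called T cell and immunoglobulin genes were also mostly higher within the plain IDs. All 17 of 17 T cell list members rose (median 0.71), with the T cell receptor chain Trbc2 at 0.72 and the signalling adaptor Lat at 0.77, and 13 of 13 regulatory T cell list members rose (median 0.77), with Lrrc32 at 1.00. Lrrc32 is also expressed by platelets. The immunoglobulin constant region list had 8 of 11 members higher (9 over the list alone). Igkc, the kappa light chain, rose from 1483 ± 273 CPM (SD, n = 8) to 2413 ± 192 CPM (SD, n = 4), a log2 fold change of 0.68. Of 225 immunoglobulin and T cell receptor genes tested, 87 rose and 1 fell (two-sided Fisher's exact p = 1.09e-12 for the share that rose). That test counts genes that may vary together as independent. In camera with an estimated correlation neither the T cell nor the immunoglobulin constant region list passed (adjusted p = 0.352 for each). The follicular and marginal zone B cell list had 3 of 17 members higher (2 over the list alone, median 0.47, camera adjusted p = 0.00252, adjusted p = 0.509 with an estimated correlation). The plasma cell list had 11 of 15 higher and the interferon gamma and antigen presentation list 16 of 24 (20 over the list alone). The NK and cytotoxic list had 3 of 21 higher and 2 lower (1 and 1 over the list alone), Klra4 (from 2.15 to 1.08 CPM) among those lower. In glycolysis 10 of 16 rose and 1 fell, Pkm, a pyruvate kinase gene, having a log2 fold change of 0.78.

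The erythroid list had 21 of 21 members lower within the plain IDs (median -1.33). Car1 fell from 734 ± 117 CPM (SD, n = 8) to 250 ± 28.1 CPM (SD, n = 4), a log2 fold change of -1.57 ± 0.13 (SE, adjusted p = 7.37e-06), and the membrane protein gene Rhag had -1.46. Tfrc, the transferrin receptor through which red cell precursors take up iron, had -1.40, the iron transporter gene Slc11a2 had -1.14, and Erfe, the erythroid hormone that lowers hepcidin, had -2.07 ± 0.32 (SE). In the cell cycle list 26 of 26 fell (median -1.11), with Pcna, the DNA polymerase clamp, at -1.28, Rrm2 at -1.37 and the thymidylate synthase gene Tyms at -1.24. Of the nuclear oxidative phosphorylation list 20 of 22 fell (21 over the list alone, median -0.50), such as Ndufv1 (-0.85). Of the ribosomal protein list 23 of 28 fell (25 over the list alone, median -0.36), such as Rps2 (-0.75). The size of falls depended on the scaling. As a share of the library total, ribosomal protein genes held 6.05% in control and 5.87% in gluten-free plain IDs (exact permutation p = 0.147, unadjusted). The erythroid mean was 10.3 and 9.36 log2 CPM of the library total, against 10.4 and 9.14 with TMM scaling. Of 809 processed pseudogenes 214 fell and 13 rose. The share that fell, 26.5%, was near the 25.0% of protein-coding genes (two-sided Fisher's exact p = 0.0164 against all other tested genes). The share that rose was 1.61%, against 21.1% of protein-coding genes (two-sided Fisher's exact p = 2.12e-54 against all other tested genes).

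By fold, the 10 highest called genes of the plain IDs were Saa3, an acute phase gene (from 1.13 to 7.48 CPM, log2 fold change 2.72 ± 0.45, SE), Prss57, a neutrophil protease gene (2.04), Igll1, the surrogate light chain gene of B cell precursors (1.99), Mpo, Epx, the eosinophil peroxidase (1.91), Kcnk12 (1.89), Mgam (1.87), Mogat2 (1.85), Prtn3 and Abca13 (1.83). The 10 lowest were Erfe, Ranbp17 (-1.87), the histone gene Hist1h1b (-1.83), Rnf212 (-1.81), Gm14862 (-1.77), Cldn20 (-1.76), the tachykinin gene Tac2 (-1.73), Syt14 (-1.71), 6030468B19Rik (-1.70) and Plek2, an erythroblast gene (-1.69). These 20 genes were chosen after the values had been seen.

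Of the 48 lists 32 passed in camera within the plain IDs (25 higher, 7 lower). In fry and in the exact permutation test of list means 35 passed, where the smallest possible p of 0.00202 gave an adjusted p of 0.0051. These 2 tests ask only whether the members differ by diet, not whether they differ more than other genes. With 7288 of 17600 genes called, a list can pass them without standing out. With an estimated correlation 0 passed (smallest adjusted p = 0.205, and adjusted p = 0.352 with an estimated correlation for the neutrophil, megakaryocyte, T cell, regulatory T cell, erythroid, cell cycle, oxidative phosphorylation, ribosomal protein, immunoglobulin, plasma cell, monocyte, mast cell and glycolysis lists). With the mean of the erythroid genes as a covariate the count of genes fell from 7288 to 471.

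**Figure D1:**
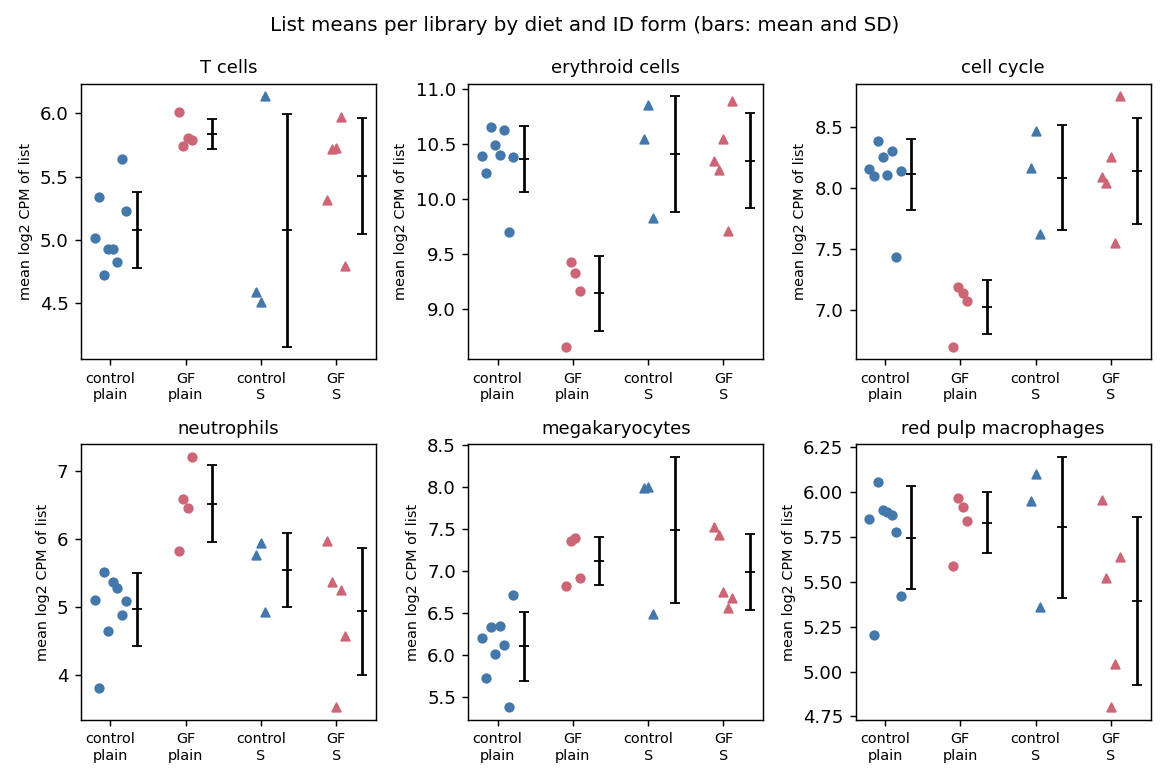
Mean log2 CPM of the genes of 6 lists in each library (vertical axes, log2 CPM), by diet and ID form, with circles for plain IDs, triangles for S IDs, and bars for the mean and SD. In the plain IDs the gluten-free erythroid mean was 9.14 against 10.4 in control, and in the S IDs 10.3 against 10.4.

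Within the S IDs (3 control and 5 gluten-free libraries) the diets were not separated: 0 genes were called in edgeR (904 at an unadjusted p under 0.05, smallest adjusted p = 0.748), 4 in DESeq2, lower with the gluten-free diet, and 0 in limma-voom. The 10 genes with the smallest pooled p-values were named only if both ID forms had the same side. Of these, Thbs4 had a log2 fold change of 1.40, Il33 0.83, Cxcl9 0.76, Lyz1 0.63 and Ssh1 -0.26 (adjusted p = 0.916 for each). Among other genes named for the pooled comparison, Il10, Xist, Rrm2, Mcm2, Prtn3 and Mpo lay on the opposite side in the S IDs. Neutrophil genes had a median of -0.49, megakaryocyte genes -0.63, erythroid genes -0.03, cell cycle genes 0.05 and T cell genes 0.28. Mesothelium and adipocyte genes had medians of -1.35 and -1.08. In camera 17 lists passed (6 higher, 11 lower), but 0 with an estimated correlation (smallest adjusted p = 0.856 with an estimated correlation) and 0 in the exact permutation test of list means (smallest adjusted p = 0.735).

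The test of the difference itself, the interaction of diet and ID form, called 4516 genes, 2701 with a higher and 1815 with a lower fold change in the S IDs than in the plain IDs. Neutrophil, megakaryocyte, erythroid, cell cycle, ribosomal protein and oxidative phosphorylation genes were among the groups that differed by fry, none of them with an estimated correlation. In the neutrophil list 19 of 20 members had a lower fold change in the S IDs (fry adjusted p = 0.0135), with Mpo differing by -2.28 and Ltf by -2.31 on the log2 scale, and in the megakaryocyte list 13 of 14 (fry adjusted p = 0.0146, and adjusted p = 0.422 with an estimated correlation for both). In the erythroid list 16 of 21 had a higher fold change in the S IDs (fry adjusted p = 0.0145), Car1 by 1.43, and in the cell cycle list 25 of 26 (fry adjusted p = 0.0135), Rrm2 by 1.47 (adjusted p = 0.422 with an estimated correlation for both). Fold changes were also higher in the S IDs in 20 of 28 ribosomal protein genes and 15 of 22 nuclear oxidative phosphorylation genes (fry adjusted p = 0.0103 for each), and lower in 4 of 9 anti-inflammatory cytokine genes (fry adjusted p = 0.00177), 8 of 10 mesothelium genes (median difference -2.16, fry adjusted p = 0.0146) and 8 of 15 fibroblast genes (fry adjusted p = 0.0135, and adjusted p = 0.422 with an estimated correlation for these 5 lists). T cell genes differed in 1 of 17 (fry adjusted p = 0.53). Fry called 17 of 48 lists and camera 19, and 0 passed with an estimated correlation (smallest adjusted p = 0.422 with an estimated correlation). With the erythroid mean as a covariate 1584 genes were called.

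Libraries with S and with plain IDs were compared to describe how far the ID forms differed. With diet as a term and its effect taken as the same in both ID forms, 1609 genes were called, 950 higher and 659 lower in the S IDs. As the interaction called 4516 genes, this count averages unlike differences over the diets. Genes without a settled annotation (to be experimentally tested in the annotation's terms) were lower in the S IDs in 131 of 526 cases (24.9%, Fisher's exact p = 6.93e-72), antisense genes in 54 of 583 (Fisher's exact p = 9.62e-10), and processed pseudogenes were higher in 82 of 809 (Fisher's exact p = 3.95e-08). These tests count genes that may vary together as independent, so the small p-values overstate the evidence. The mitochondrial genome list was higher in the S IDs (median log2 difference 0.96, camera adjusted p = 3.59e-12), as were erythroid (0.74), megakaryocyte (0.72) and cell cycle genes (0.56). Of the 48 lists camera called 16, with 12 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.534 with an estimated correlation). In the control libraries alone the erythroid mean was 10.4 ± 0.30 log2 CPM (SD, n = 8) in plain and 10.4 ± 0.52 (SD, n = 3) in S IDs. The cell cycle mean was 8.11 ± 0.29 (SD, n = 8) and 8.08 ± 0.43 (SD, n = 3), and the megakaryocyte mean 6.10 ± 0.41 (SD, n = 8) and 7.49 ± 0.87 (SD, n = 3). The differences among the controls were not tested. The count rested on single libraries: it was 575, 713, 718 and 623 without gluten-free 7, 8, 9 and 10, 653 and 4378 without control S2 and S6, and 962, 914, 884 and 970 without gluten-free S1, S3, S5 and S8. It was 2846 in DESeq2 and 595 with sex genes as a covariate. As the Y-linked genes had almost no counts, that covariate followed the level of Xist and did not separate males from females.

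The first principal component of log2 CPM held 28.7% of the variance and the second 14.4%. The shares of a few RNA classes followed the ID form with 1 exception. Genes similar to ribosomal RNA held 0.581% to 0.803% of counts in the plain IDs and 0.110% to 0.253% in the S IDs, except that control 5, a plain ID, had 0.179%. Malat1, a nuclear non-coding RNA, held 0.106% to 0.231% in the other plain IDs, 0.0594% in control 5 and 0.0526% to 0.0780% in the S IDs. Within the plain IDs it also differed by diet (0.125% in control, 0.188% in gluten-free libraries, exact permutation p = 0.0242, unadjusted), as did the count of genes detected (23488 and 24665, exact permutation p = 0.0121, unadjusted). The rRNA-like share did not with control 5 (exact permutation p = 0.834) and did without it (exact permutation p = 0.0152, both unadjusted). Without control 5, 7335 genes were called between the diets within the plain IDs.

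**Figure D2:**
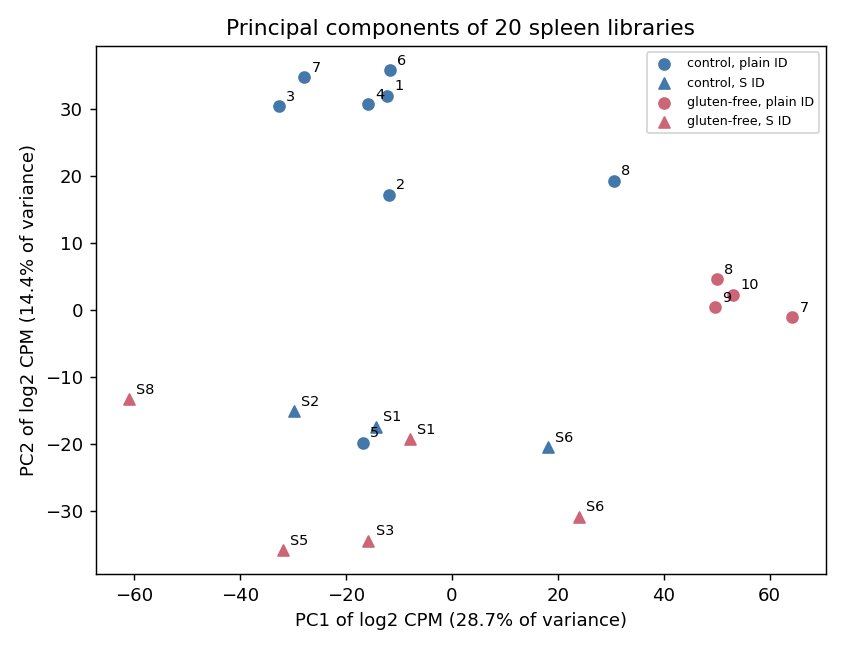
First and second principal components of log2 CPM (horizontal and vertical axes, 28.7% and 14.4% of the variance), with colours for diet, circles for plain IDs, triangles for S IDs, and the ID beside each library. The 4 gluten-free libraries with plain IDs lie between 49.7 and 64.3 on the first component, and control 5 lies at -19.8 on the second, among the S IDs.

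**Figure D3:**
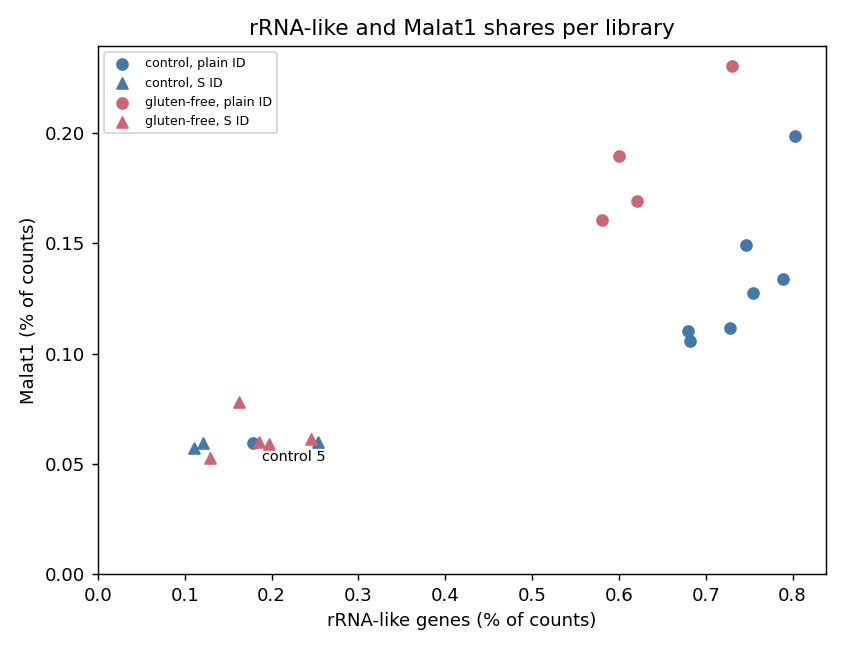
Percent of counts from genes similar to ribosomal RNA (horizontal axis) and from Malat1 (vertical axis) in each library, with colours for diet, circles for plain IDs and triangles for S IDs. Control 5, at 0.179% and 0.0594%, is named in the plot.

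Library composition was compared between the diets by exact permutation with adjustment over 6 measures. The library total was higher in gluten-free libraries (exact permutation p = 0.0013, adjusted p = 0.00782, and p = 0.00343 within the ID forms). Within the plain IDs it averaged 16071300 ± 2167680 counts (SD, n = 8) in control and 19553600 ± 2650290 (SD, n = 4) in gluten-free libraries (exact p = 0.0343), and within the S IDs 16959300 ± 1492720 (SD, n = 3) and 20649100 ± 2479760 (SD, n = 5, exact p = 0.0357). Immunoglobulin genes held 0.575% of counts in control and 0.729% in gluten-free libraries (adjusted p = 0.291, exact permutation). Within the plain IDs the immunoglobulin share was 0.559% ± 0.120 (SD, n = 8) and 1.08% ± 0.0276 (SD, n = 4, exact p = 0.00202, the smallest possible), and within the S IDs 0.617% ± 0.124 (SD, n = 3) and 0.447% ± 0.179 (SD, n = 5, exact p = 0.179). Haemoglobin genes held 13.6% and 11.2% (adjusted p = 0.196, exact permutation), with 13.3% and 9.17% within the plain IDs (exact p = 0.0364, and 0.0727 without control 5) and 14.4% and 12.9% within the S IDs (exact p = 0.518). Mitochondrial genome transcripts held 1.74% and 2.45% (adjusted p = 0.121, exact permutation), with 1.56% and 1.68% within the plain IDs (exact p = 0.628) and 2.23% and 3.07% within the S IDs (exact p = 0.179). Ribosomal protein genes held 5.82% and 5.78% (adjusted p = 0.874, exact permutation), with 6.05% and 5.87% within the plain IDs (exact p = 0.147) and 5.22% and 5.71% within the S IDs (exact p = 0.321). Pancreatic acinar genes, which mark the neighbouring pancreas, held 0.0125% and 0.154% (adjusted p = 0.348, exact permutation), the latter mean resting on gluten-free S1 at 1.37%.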

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

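The tests of the erythroid share, of the library size of control 5 and of the acinar genes were chosen after the result had been seen, and the fits within the ID forms with covariates were added at the same time. The other tests of this part were set earlier, except that the criterion for the score of control 5 was made stricter once its value was known.

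The diet difference itself differed between the ID forms: the interaction called 4516 genes. Of 72 named genes 40 passed it. Many of the 72 were named for large fold changes in the plain IDs, so differences of the opposite sign in the S IDs are partly built into that choice, unlike in the 4516 of all genes. The values that follow are log2 fold changes in the S IDs minus those in the plain IDs. Myeloid, platelet and inflammatory genes had lower fold changes in the S IDs: Saa3 -3.20, Epx -3.70, Prss57 -2.40, Mpo -2.28, Prtn3 -1.90, Ltf -2.31, Chil3 -2.31, Lyz2 -0.89, F13a1 -2.06, Mcpt8 -2.22, Thbs1 -1.72 and F5 -1.87. So had Abca13 (-2.56), Mgam (-2.44), Mogat2 (-2.27), Lat (-0.79), Lrrc32 (-1.58), Igkc (-1.21) and Pkm (-0.92). Red cell and iron genes had higher fold changes in the S IDs: Car1 1.43, Tspo2 1.31, Rhag 1.5, Tfrc 1.48, Slc11a2 1.22, Erfe 3.49 and Plek2 2.10. Genes of DNA replication and chromatin did too: Rrm2 1.47, Mcm2 1.21, Pcna 1.47, Tyms 1.35 and Hist1h1b 1.84. The others were Ranbp17 1.72, Rnf212 1.93, Gm14862 2.22, Cldn20 2.25, Tac2 1.85, Syt14 1.79, 6030468B19Rik 1.91, Ndufv1 0.93 and Rps2 0.87.

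Chance assignment of the libraries was tested with other splits. The 7288 genes within the plain IDs were reached by 1 of 100 splits, the real one (highest other 4793). The 4516 of the interaction were also reached by 1 of 100 (highest other 2578). That makes chance unlikely for both but does not exclude it, since 100 splits cannot show a share under 1 in 100. The 1609 genes between the ID forms were reached by 1 of 100 splits as well (highest other 0), with the same limit. For the 27 lists of the pooled diet comparison chance stays open, since 8 of 100 splits gave at least as many (highest other 30, median 15). Where the real count was 0 genes every split reaches it, so the 100 of 100 splits of the pooled comparison (highest other 1) and the 56 of 56 of the S IDs (highest other 402) say nothing about chance. The 402 genes belong to the split picked as the highest of the S IDs, where the median was 0. Whether they reflect a structure among the S libraries was not tested.

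For the large diet difference within the plain IDs, a lower share of red cell precursors as the whole cause would raise the other cell types alike. The neutrophil list mean was higher by 1.55 and the red pulp macrophage list mean by 0.083 log2 CPM. These differences lay 1.47 apart (exact permutation p = 0.00202, SD of the difference 0.373 in 8 control and 0.478 in 4 gluten-free libraries), so these 2 lists did not rise alike. Both lists were chosen after their values had been seen, so the small p was partly built into the choice. Whether the other cell types rose alike was not tested. With the erythroid mean as a covariate 471 genes were called in place of 7288. The median absolute log2 fold change dropped from 0.59 to 0.30 and its standard error rose from 0.13 to 0.24. That covariate itself separated the diets within the plain IDs, at 9.87 or more in control and 9.60 or less in gluten-free libraries (log2 CPM of the library total). The drop therefore cannot show how much of the pattern goes with red cell precursors. A lower share of them may account for part of it. A library difference that goes with the rRNA-like share is argued against as the whole cause by 6212 genes with that share as a covariate against 7335 without it (5101 shared, control 5 left out), and greater depth by 7128 genes after thinning to 13626000 counts (6896 shared with the 7288 at full depth). The diet itself stays open, and so do litter, cage and time of collection, which the labels do not give and which cannot be separated from the diet here. Mesothelium and fibroblast genes were also higher there, and how much capsule and stroma each library held was not tested. That the S IDs showed 0 called genes leaves open which ID form is the more typical one.

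Control 5, a plain ID, had 0.179% of counts from rRNA-like genes, far from the nearest other plain control (0.679%), and within the range of the S IDs, beside whose columns its own stands in the count table. Library size is argued against, since its 16555100 counts lay within the 13626000 to 19719600 of the other plain controls. For preparation or sequencing together with the S IDs a score was made from 3033 and 2850 genes that separate the ID forms among gluten-free libraries. Those libraries also differ in composition, with an erythroid list mean of 9.14 log2 CPM in plain and 10.3 in S IDs. The score therefore cannot separate preparation from composition. Control 5 scored 2.41, within the S controls (1.82 to 2.45) and above the other plain controls (1.48 to 2.36), which met the criterion first written. These ranges overlap, and the gap of control 5 is smaller than their spread. Shared preparation remains a possible explanation and cannot be told apart from composition or chance by this score. Apart from the score, control 5 had a median correlation of 0.979 with the S controls and of 0.973 with the other plain controls. Its Malat1 share of 0.0594% lay within the range of the S IDs. These values were not tested. No biological explanation was tested.

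Pancreatic acinar genes held 1.37% of counts in gluten-free S1, far from the next of its diet group at 0.0035%, and 0.123% in control 4. Carry-over of pancreas tissue at dissection is a candidate source: 24 of 26 acinar genes in gluten-free S1 were at least 10 times their median over the other libraries, with Ctrb1 at 2255 and Pnlip at 1449 CPM, and control 4 had 227 and 121 CPM of these. Reads shared between near-identical trypsin genes are argued against, since 20 of 21 acinar genes outside that family passed the same mark. Of the acinar list 3 members were measured in the tests of lists. No biological explanation was tested.

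Single libraries also stood apart in other measures. Gluten-free 9 had an immunoglobulin share of 1.04%, below the nearest of its 4 libraries at 1.09%. Gluten-free 10 had 16.9 CPM of Abca13, 2015 CPM of Lyz2 and 513 CPM of Rps2, above the other 3 gluten-free plain IDs. Control 8 had 944 CPM of Tfrc and 287 CPM of Rrm2, below the other 7 plain controls. In all 10 of 152 sets of values (6.58%) had such a library, where chance gives about 1 in 20.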

How the results depend on the processing

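Alternatives with control 5 moved or left out, with the rRNA-like share, and within the ID forms were chosen after the data had been seen. The pooled diet count of 0 genes stayed at 0 with RLE or upper quartile scaling, a mean of at least 1 CPM, a robust fit, covariates for sex, erythroid or rRNA-like genes, a surrogate variable, protein-coding genes alone, fewer abundant genes, a 1.5-fold minimum, the S IDs alone, control 5 moved, and control 5 and gluten-free S1 left out. It was 1 with no filter, limma-voom, no term for the ID form, the acinar covariate and an adjusted p under 0.1, 1593 in DESeq2, 9572 in limma-voom with quality weights and 7296 in the plain IDs alone. Leaving out single libraries gave 0 to 3765, with 3765 without control S6, 2990 without gluten-free S8 and 1 without gluten-free S1. Of the 3765 and 2990 genes, 91.9% and 97.2% were also called in the plain IDs in the same direction. As leaving out any other single library gave 0 or 1 genes, fewer libraries alone do not account for these counts. Control S6 had the highest T cell list mean of all libraries (6.14 log2 CPM) and gluten-free S8 the highest erythroid list mean (10.9). Both values lie opposite to the diet difference of the plain IDs. The cause was not tested.

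The 27 lists became 0 with an estimated correlation, 0 in fry, 0 in the exact permutation test of list means, also within the ID forms, and 14 with the erythroid covariate; leaving out libraries gave 26 to 29. Of those 14 only megakaryocytes kept their call and direction, 6 were called the opposite way and 7 had not been called before. A replicate block over the 4 IDs found in both diets gave 0 genes (637 at an unadjusted p under 0.05 in edgeR) and 26 lists, but the numbers may not pair the libraries, since the profiles of equal IDs correlated across genes at -0.189, -0.219, 0.142 and 0.407 after group means were removed. The 1609 genes between ID forms became 2846 in DESeq2 and 595 with the sex gene covariate, which here followed the level of Xist. They ran from 575 without gluten-free 7 to 4378 without control S6. The erythroid covariate took the interaction from 4516 to 1584 genes and the plain IDs from 7288 to 471, and DESeq2 took the S IDs from 0 to 4. The plain count otherwise ran from 5945 to 8680. The cause was not tested.

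The direction turned in 16 of 1461 values of named genes in the pooled comparison, in 0 of 797 in the plain IDs, in 5 of 126 of sample measures and in 72 of 1632 of lists. The 16 and the 5 were not called before or after. As log2 fold changes, the S IDs alone gave Il10 -0.0053, Xist 0.11, Rrm2 0.12, Mcm2 0.070, Prtn3 -0.048 and Mpo -0.29. The erythroid covariate gave Foxp3 -0.14, Tnf -0.050, Xist 0.084, Rrm2 0.0059, Mcm2 0.040 and S1pr3 -0.016. The replicate block gave Ifng -0.35 and Xist 0.13, and Xist was 0.040 with no term for the ID form and 0.012 with a surrogate variable. Leaving out single libraries, the diet difference in percent ran from -0.173 to 0.0287 for ribosomal protein genes, and from -0.0109 (without gluten-free S1) to 0.160 for acinar genes.

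The lists that turned are given with camera adjusted p values. With the erythroid covariate, made from the erythroid list itself, these turned higher: erythroid cells 0.0496, cell cycle 2.52e-07, oxidative phosphorylation 0.00185, ribosomal proteins 0.0258 and iron handling 0.394. These turned lower: naive T cells 0.605, gamma-delta T cells 0.451, follicular B cells 0.00123, plasma cells 0.0421, immunoglobulin constant regions 0.160, conventional dendritic cells 0.00522, interferon gamma response 0.394, inflammatory cytokines 0.346, gut homing 0.191, immediate early genes 0.828, circadian clock 0.207, helper T cells 0.207, germinal centre B cells 0.207, fibroblasts 0.0907 and smooth muscle 0.160. Monocytes, plasmacytoid dendritic cells, anti-inflammatory cytokines, coeliac genes, NKG2D and aryl hydrocarbon receptor genes did too, at 0.966 each.

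In the S IDs alone, where fewer libraries were used, cell cycle 0.538, oxidative phosphorylation 0.0152, ribosomal proteins 0.000162 and type I interferon 0.989 turned higher. These turned lower there: plasma cells 0.0452, immunoglobulin constant regions 0.0389, neutrophils 0.000169, monocytes 0.0438, megakaryocytes 0.000602, mast cells 0.0276, anti-inflammatory cytokines 0.284, glycolysis 0.379, fibroblasts 0.000194, smooth muscle 0.0389, germinal centre B cells 0.563, conventional dendritic cells 0.422, progenitors 0.0796 and aryl hydrocarbon receptor genes 0.987. Gamma-delta T cells, circadian clock, helper T cells and NKG2D genes did too, at 0.989 each. In the plain IDs alone mesothelium 0.00624, NK cells 0.909, red pulp macrophages 0.637, unfolded protein response 0.909, adipocytes 0.879 and endothelium 0.218 turned higher, and the mitochondrial genome 0.879 and acinar cells 0.606 lower.

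With the replicate block mesothelium 0.00977 and type I interferon 0.686 turned higher. The unfolded protein response turned higher with no term for the ID form (0.868) and with control 5 moved (0.950). Acinar cells turned lower with the acinar covariate (0.736) and without control 5 and gluten-free S1 (0.279). Some single libraries left out turned 4 lists, whose p ran over all libraries left out from 0.516 to 0.973 for the unfolded protein response, 0.293 to 0.979 for acinar cells, 0.329 to 0.988 for endothelium and 0.235 to 0.976 for mesothelium. The cause was not tested.

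Of 1461 values of 36 named genes in the pooled comparison 1285 kept their direction and side of the threshold and 160 newly passed it; of 797 values of 42 genes in the plain IDs 763 kept it and 34 lost it, 27 of them with the erythroid covariate. Of 126 values of sample measures 108 kept both. In the pooled comparison the chromosome distribution had no called genes to place. For simulated 1.5-fold changes recovery was lowest in the interaction and the S IDs, at 5.97% and 10.4%. For 4-fold changes it was 72.7% in the interaction and 90.9% in both the S IDs and the plain IDs.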

Other observations

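Nothing in this part was tested as an explanation, and the lists within the plain IDs were described after their values had been seen. Within the plain IDs several lists not described there moved as well, counted over all genes and then adjusted over the list alone. Higher members were found in 12 of 18 coeliac disease associated genes (14 over the list alone, 1 lower in both), 7 of 9 anti-inflammatory cytokine genes (7), 7 of 10 plasmacytoid dendritic cell genes (7) and 7 of 11 germinal centre B cell genes (8, 1 lower in both). Conventional dendritic cells had 7 of 13 higher (7, 1 lower in both), the circadian clock 7 of 16 (7), and the immediate early genes 10 of 20 (11, 2 lower in both). Fatty acid oxidation had 9 of 17 lower (9). Each of these lists passed camera in the plain IDs, and 0 did with an estimated correlation (smallest adjusted p = 0.205 with an estimated correlation, for the anti-inflammatory list).

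Stress and interferon lists went both ways within the plain IDs, where 21.1% of protein-coding genes were called higher and 25.0% lower. The interferon and unfolded protein response lists lay near those shares, so their counts do not set them apart from other genes. The type I interferon response had 5 of 23 members higher and 5 lower (5 and 5 over the list alone, camera adjusted p = 0.660), and the unfolded protein response 3 of 16 higher and 5 lower (3 and 5, camera adjusted p = 0.919). Heat shock had 1 of 14 higher and 5 lower (1 and 5, camera adjusted p = 0.0428, adjusted p = 0.602 with an estimated correlation). Control 8 lay nearest to the gluten-free plain IDs on the first principal component among the controls, at 30.6, and gluten-free S8 lay farthest from them, at -61.0. Their erythroid list means were 9.69 and 10.9 log2 CPM.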
